A study of Homo sapiens with 2 samples.

How the data were processed

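RNA was measured in 2 libraries of T47D, a human luminal breast cancer cell line that carries estrogen and progesterone receptors. One library came from cells transduced with a non-targeting short hairpin (shNT) and the other from cells transduced with a hairpin against RON (shRON), the receptor tyrosine kinase encoded by MST1R. Per the labels' protocols, transduced cells were selected in 5 ug/mL puromycin and kept in 1 ug/mL, grew in high-glucose DMEM with 10% serum, and gave TRIZOL-extracted total RNA from which TruSeq RNA libraries were made. Whether that kit marked strand is not given in the sources used here. The group of each library was taken from its treatment label. The name of the control library's table describes the cells as wild type, whereas its label gives a non-targeting hairpin. The label was followed, and whether the control cells carried a hairpin was not settled from the data. Both table names carry the same run and lane.

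Each deposited table lists 37839 RefSeq transcripts of 25240 genes in the layout of Cufflinks, per the file headers, with the build hg19 per the submitters' processing notes. The submitters' processing notes also name DESeq, without a role or version. The aligner and the version of Cufflinks are not given in the sources used here. The deposited FPKM values were read, from their column name, as fragment numbers divided by transcript length and by the library's fragment total. No scaling between the libraries is stated. The deposited coverage was read, from its column name, as the mean read depth over the bases of a transcript, not divided by library size. Its ratio to FPKM lay between 2 bounds that differed by a factor of 2.00 in each library, which is what single and paired reads of 1 fragment would give. No confidence intervals of FPKM were among the columns used. Each transcript also carries a status: 6 transcripts in shNT and 0 in shRON were marked FAIL, and 94 in each library LOWDATA.

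Coverage multiplied by transcript length summed to 2.90 gigabases in shNT and 2.77 in shRON. Among long genes with a single transcript whose ratio of coverage to FPKM was at the upper bound, the median of products between 150 and 325 bases was 244 bases in shNT (280 genes) and 241 bases in shRON (275 genes), which was taken as the bases contributed by 1 read pair. At the lower bound, products of 116 bases in shNT (84 genes) and 124 in shRON (55 genes) were the median between 80 and 150 bases, and were taken as single reads. The quartiles of the products taken as pairs were 226 and 263 bases in shNT and 223 and 262 in shRON. The bounds of both ranges were set values, which partly fix these medians. Dividing each product by the pair median of its library gave estimates of fragments per gene, which carry that uncertainty. Only 27.3% of low values in shNT and 26.0% in shRON lay within 0.1 of a whole number of such pairs, against 20.0% by chance, so whole reads were not recovered and no count test was run. Intervals given beside single genes are 95% Clopper-Pearson intervals on these estimated fragments. They are approximate and cover counting error only, not the difference between cultures.

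Transcript values were summed per gene. Genes with 1 FPKM or more in at least 1 library were kept, and small RNA genes, which such libraries capture poorly, were left out, leaving 12484 genes. The log2 ratio of a gene is log2 of FPKM + 1 in shRON over FPKM + 1 in shNT, a scale that understates the ratio of genes with low values. Genes were counted as higher or lower by a fixed rule of size, 2-fold on this scale. With 1 library per group there is no replicate check, so no p-value and no standard error of a difference between conditions is given, and every difference describes these 2 libraries.

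The 32 gene lists were fixed before the data were examined, as were the size rules, the rule for named genes and most alternative settings. A list needed 5 measured members. A measured member could reach 1 FPKM in 1 library only, and such a member is higher in that library by construction. Its median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression by drawing from windows of 200 genes. The percentile is a description of these libraries, and values above 97.5 or below 2.5 are called outside the central range. Members were counted as higher or lower at 1.5-fold. The lists held interferon-stimulated, MHC class I and NF-kB genes; estrogen-response, progesterone- and glucocorticoid-response, luminal, basal and mesenchymal, stem-cell-associated and beta-catenin/TCF genes; cholesterol synthesis, fatty acid synthesis, LXR, glycolysis, hypoxia and oxidative phosphorylation genes; G1/S, mitosis, histone, p53, apoptosis, MAPK and immediate-early genes; ER chaperone, ATF4, heat-shock, TGF-beta and YAP, ribosomal protein and RNA interference genes; RON with its ligand and ligand-processing genes; and markers of fibroblasts, immune cells and endothelium. Named genes were MST1R, MST1, MET, ESR1, PGR and GATA3, the 12 genes with the highest and the 12 with the lowest log2 ratio among those at 5 FPKM or more in at least 1 library (names starting LOC or containing orf left out), and up to 4 members of each list with the largest absolute log2 ratio. The part of that rule that used deposited intervals did not apply. Genes named outside the rule are said to be so.

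Positions are those of the deposited tables on hg19, written with a 1-based start. The lengths of 3640 single-exon transcripts matched a 0-based start in the tables and 0 matched a 1-based start. Of the 12484 genes, 11755 (94.2%) matched a GENCODE gene on GRCh37 through symbols, older symbols or RefSeq accessions, which supplied strand, gene type and GC content. Of 11742 such genes on 1 chromosome, 11734 (99.9%) overlapped their GENCODE position. Medians were also taken over bins of 10 Mb with at least 15 genes and compared with 1000 shuffles of the gene positions, and neighbouring genes up to 500 kb apart were compared with 10000 shuffles. These position summaries were added after the values had been seen.

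Alternatives changed the pseudocount (0.1 and 5), the scaling (equal totals, or log2 ratios centred on their median), the summing of transcripts, the FPKM filter and the handling of small RNA genes. Added after the data had been seen were leaving out transcripts whose status was not OK, requiring about 50 estimated fragments, removing a trend with gene length, GC content and expression, and subtracting from each gene the median of the other measured genes within 5 Mb, called its regional median (at least 10 such genes). The steps were tested on simulated data with 12484 genes drawn from the real levels. For the comparison of shRON with shNT, all genes made 4-fold higher were recovered (100%), as were 89.0% of those made 4-fold lower, or 100% of those with a mean of 5 FPKM or more, and 0 unchanged genes were called. Of unchanged lists of 20 genes, 5.5% fell outside the central range, and 100% of lists shifted by 0.5 on the log2 scale lay above it. The simulated data held counting error only, at the same number of fragments per FPKM for every gene. They had no variation between cultures and no regional shifts. They therefore do not show how many calls in the real libraries would recur in other cultures. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.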

Results

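The series compared the transcriptomes of T47D cells with and without a hairpin against RON, 1 library per group, to ask which transcripts differ when RON is reduced. RON is the receptor for macrophage-stimulating protein, the product of MST1. The values rested on about 11900000 estimated fragments in shNT and 11500000 in shRON. The depth of shNT over shRON, taken from the lower bounds of coverage over FPKM, was 1.04. FPKM summed to 398372 in shNT and 382330 in shRON, and 11975 and 12155 genes reached 1 FPKM. The 10 most abundant genes took 6.54% of the total in shNT and 6.33% in shRON. Across the 12484 measured genes, log2(FPKM + 1) of both libraries correlated with a Pearson r of 0.955, over genes that are not independent replicates.

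MST1R, the hairpin's target, was 25.1% lower in the shRON library. It stood at 12.1 FPKM in shNT and 9.10 FPKM in shRON, a log2 ratio of -0.38, from an estimated 844 and 629 fragments. The ratio of FPKM was 0.749, with an approximate counting interval of 0.675 to 0.832. The direction goes with the labels, but 17.7% of all measured genes were lower by more than MST1R. The gene lies on the minus strand of chromosome 3 from 49924435 to 49941306 and is protein-coding, with 1 transcript in the table. Its regional median was 0.18, and relative to it MST1R was at -0.56. MST1 was low, at 1.39 FPKM in shNT and 2.20 in shRON (log2 ratio 0.42), and MET, which encodes the related HGF receptor, stayed at or under 0.0641 FPKM in both. Of the 6 measured genes of the list of RON, its ligand and ligand-processing proteins, 2 were at least 1.5-fold lower, HPN (16.6 to 9.86 FPKM, -0.70) and SPINT1 (223 to 141 FPKM, -0.66, with a regional median of -0.33). The list median of -0.28 was at percentile 9.35. Membership of this list does not say whether a gene promotes or inhibits processing of the ligand, so the 2 lower members give no direction for it.

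By the rule of 2-fold, 415 genes (3.32%) were higher and 271 (2.17%) lower in the shRON library. Most log2 ratios were small, with quartiles at -0.25 and 0.30 and a median of 0.04. Apart from DDX17, the 12 highest ratios belonged to genes at or under 2.77 FPKM in shNT. CLEC2B, a C-type lectin gene on chromosome 12 (10004968 to 10022458), stood at 0.147 FPKM in shNT and 28.2 in shRON, and its neighbours CLEC7A (0.673 to 16.7) and OLR1 (0.649 to 12.8) were also higher, while CLEC2A was listed at 0 in shNT and at 10.1 in shRON. The cancer-testis antigen genes MAGEA6 (0.818 to 28.2 FPKM, 4.01) and MAGEA12 (1.95 to 23.5, 3.05), the chemokine gene CXCL10 (1.26 to 29.7, 3.77), the chemokine receptor gene CXCR4 (0.840 to 19.5, 3.47), the interferon-induced GTPase gene MX2 (2.32 to 38.1, 3.55) and the aldo-keto reductase genes AKR1C2 (2.77 to 35.5, 3.28) and AKR1C1 (1.96 to 27.0, 3.24) completed the group with DDX17. DDX17 was listed at 0 in shNT and at 112 FPKM in shRON, but all 4 of its transcripts carried the status FAIL in shNT, so its 0 is a failed estimate. MAGEA6 and MAGEA12, and AKR1C1 and AKR1C2, are near-identical to relatives, and how reads were divided among them is uncertain.

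The lowest ratios belonged to genes that were well expressed in shNT, which a large fall on the FPKM + 1 scale requires. KCTD3 was at 119 FPKM in shNT and 10.3 in shRON (log2 ratio -3.41), and the potassium channel gene KCNK2, its neighbour on chromosome 1 (215178885 to 215410436), was at 85.3 and 8.43 (-3.19). EEF1A2, a translation elongation factor gene, was at 153 and 16.6 FPKM (-3.13), SNCG, which encodes gamma-synuclein, at 114 and 13.7 (-2.97), and the tight-junction gene CLDN1 at 432 and 58.9 (-2.85). The ratio of FPKM of CLDN1 was 0.136, with an approximate counting interval of 0.131 to 0.142. MXRA8 (47.5 to 4.86 FPKM), GRIK3 (10.3 to 0.900), TNNT1 (39.0 to 5.97), the matrix glycoprotein gene THBS1 (61.8 to 10.2), FKBP10 (16.8 to 2.21) and the calcium channel gene CACNA1H (18.1 to 2.44) were lower by a log2 ratio of -3.05 to -2.47. PYCARD, which encodes an inflammasome adaptor, was at 10.6 FPKM in shNT and listed at 0 in shRON, the lowest ratio of this group. The counts of 415 and 271 were 696 and 490 with a pseudocount of 0.1, and 145 and 84 with a pseudocount of 5.

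**Figure D1:**
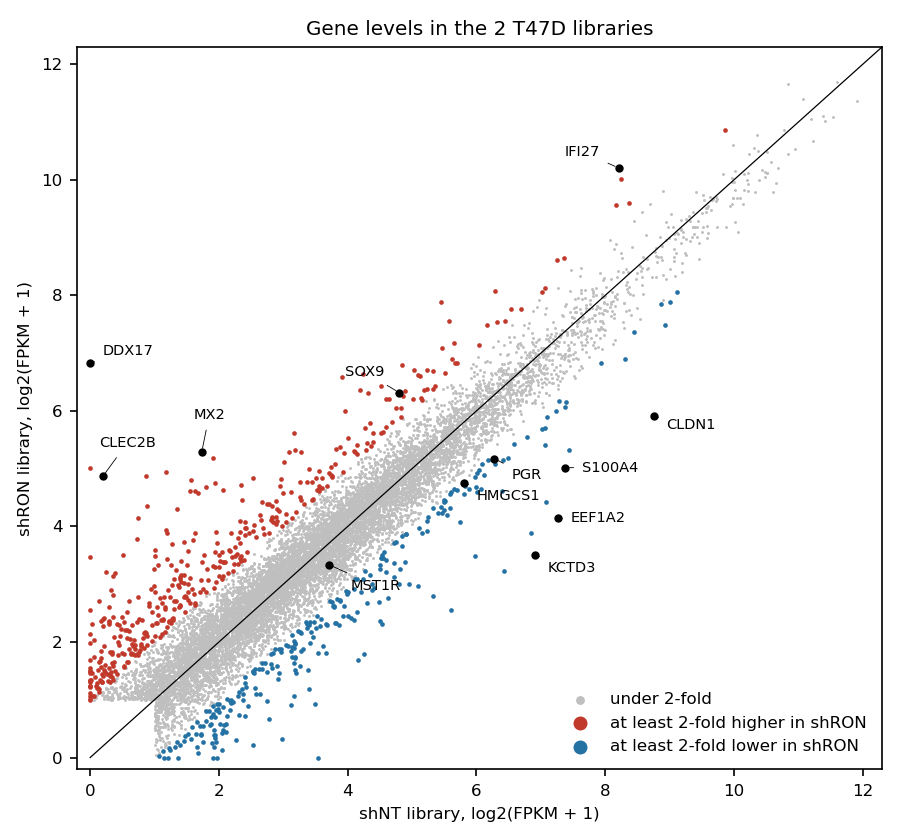
Levels of the 12484 measured genes in both libraries, as log2(FPKM + 1), 1 point per gene, with shNT on the horizontal axis, shRON on the vertical axis and the line of equal levels. The 415 red points are at least 2-fold higher and the 271 blue points at least 2-fold lower in shRON, MST1R lies just under the line (12.1 against 9.10 FPKM), and DDX17 is at 0 in shNT because its estimate failed there.

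Interferon-stimulated genes were higher in the shRON library as a group. All 32 measured members had log2 ratios above 0, 30 of them reached 1.5-fold and 23 reached 2-fold. MX2, HERC5, which encodes the ligase for the ubiquitin-like protein ISG15 (2.81 to 26.0 FPKM, 2.82), the antiviral gene RSAD2 (4.05 to 25.4, 2.39) and IFI27 (296 to 1178, 1.99) had the largest ratios. The ratio of FPKM of IFI27 was 3.98, with an approximate counting interval of 3.81 to 4.16. The list median of 1.30 lay above all 10000 matched random medians.

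Genes of MHC class I presentation and NF-kB target genes were also higher. Of 13 presentation genes, 9 were at least 1.5-fold higher and 0 lower (median 0.84). They included the peptide transporter genes TAP2 (14.4 to 37.8 FPKM, 1.33) and TAP1 (64.9 to 140.5, 1.10), HLA-F (28.1 to 57.1, 1.00) and the immunoproteasome gene PSMB9 (17.5 to 34.8, 0.95). Of 18 NF-kB and cytokine genes, 16 were at least 1.5-fold higher and 1 lower (median 1.10), led by the chemokine gene CCL20 (1.26 to 14.3 FPKM, 2.76), TNFAIP2 (18.8 to 78.8, 2.01), the mitochondrial superoxide dismutase gene SOD2 (27.9 to 110.1, 1.94) and IL32 (5.35 to 20.5, 1.76). Both medians lay above all 10000 matched random medians. HLA genes share sequence with one another, and TAP1 overlaps a measured noncoding gene, so these values are uncertain. Of the markers of immune cells, 1 of 13 reached 1 FPKM: CD68, a lysosomal gene, was at 1.37 FPKM in shNT and 5.84 in shRON, while PTPRC, LYZ, CD3E and TYROBP were listed at 0 in both libraries. Of the fibroblast markers, COL1A1 was at 3.95 and 4.27 FPKM and COL3A1 at 0.0103 and 1.53, and of the endothelial markers ENG was at 7.21 and 7.65.

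Genes of cholesterol synthesis and uptake were lower in the shRON library. Of 24 measured members, 23 had log2 ratios below 0, 11 were at least 1.5-fold lower and 0 were higher by that size. The largest differences were those of HSD17B7 (8.05 to 2.96 FPKM, -1.19), the squalene synthase gene FDFT1 (135 to 58.7, -1.19), the sterol carrier gene STARD4 (12.8 to 5.12, -1.17) and HMGCS1, an early enzyme of the mevalonate pathway (55.2 to 25.9, -1.06). The list median of -0.51 lay below all 10000 matched random medians. FDFT1 lies in a region whose other genes were lower too, with a regional median of -0.58. HMGCS1 does not, with a regional median of -0.02 and a ratio of FPKM of 0.470 (approximate counting interval 0.440 to 0.502).

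The medians of fatty acid synthesis, glycolysis and hypoxia genes also lay below the central range, while those of LXR targets and oxidative phosphorylation genes lay inside it. Of 12 fatty acid synthesis genes, 5 were at least 1.5-fold lower and 2 higher (median -0.41, percentile 0.31). The desaturase gene SCD (467 to 230.2 FPKM, -1.02, regional median -0.48), ACACA (-0.82) and ACLY (135 to 78.7, -0.77) were lower, and THRSP, which overlaps the measured gene NDUFC2, was higher (4.86 to 15.3, 1.47). With a pseudocount of 5 the list was at percentile 3.74. Of 17 glycolysis enzymes, 5 were lower and 1 higher by 1.5-fold (median -0.42, percentile 0.1, or -0.27 at percentile 1.98 with a pseudocount of 5). LDHA was at 475 and 240.0 FPKM (-0.98), PGAM1 at 347 and 164 (-1.08, regional median -0.49), and ALDOC had a log2 ratio of -1.26, whereas LDHB was at 1.27 and 13.7 (2.69). Of 17 hypoxia genes, 5 were lower, among them AK3L1 (-0.79) and ADM (-0.77), and 2 were higher, EGLN3 (1.39 to 9.11 FPKM, 2.08) and VEGFA (24.7 to 55.0, 1.13), with a median of -0.32 at percentile 0.295. Among 8 LXR targets, 1 was lower by 1.5-fold, APOE (284 to 148 FPKM, -0.93), and the median of -0.06 was at percentile 27.8, or -0.24 at percentile 4.04 with regional medians subtracted. Of 39 nuclear genes of oxidative phosphorylation, 5 were lower, including COX7C (-0.83, regional median -0.50) and UQCRC2 (-0.77), and the median of -0.21 was at percentile 6.94, or 2.32 after regional medians were subtracted, and was -0.09 with the trend removed.

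Hormone-response genes went both ways. ESR1, the estrogen receptor gene, was at 36.7 FPKM in shNT and 23.7 in shRON (-0.61), and PGR, the progesterone receptor gene and itself an estrogen target, at 76.7 and 35.1 (-1.11), with a ratio of FPKM of 0.458 (approximate counting interval 0.445 to 0.471). Of 31 estrogen-response genes, 15 were at least 1.5-fold lower and 1 higher (median -0.27, percentile 0.12). The median was -0.60 with the 28 members at 5 FPKM or more and -0.45 with regional medians subtracted, both below all matched random medians. The largest differences were in AGR3 (52.8 to 15.8 FPKM, -1.67), SUSD3 (19.7 to 6.50, -1.47, regional median -0.49), PDZK1 (8.06 to 2.32, -1.45) and CA12 (165 to 66.0, -1.31), while GREB1, a classical target named here after its values were seen, was at 48.1 and 47.5. Of 11 progesterone- and glucocorticoid-response genes, 6 were higher and 0 lower by 1.5-fold (median 0.74, above all matched random medians), among them STAT5A (1.76 to 7.97 FPKM, 1.70), S100P (27.4 to 65.5, 1.23) and TSC22D3, which encodes the glucocorticoid-induced leucine zipper (8.67 to 21.1, 1.19).

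The measured markers of basal and mesenchymal cells were mostly higher, while the median of luminal markers was close to 0. Of 16 luminal markers, 2 were higher, ELF3 (16.6 to 41.7 FPKM, 1.28) and MLPH (41.2 to 65.1, 0.65), and 2 lower, ESR1 and CDH1, which encodes E-cadherin (163 to 100.1, -0.70, regional median -0.36). Their median of 0.06 was at percentile 92.5, and was -0.11 after regional medians were subtracted. The luminal transcription factor gene GATA3 was at 223 and 269 FPKM (0.27). Of 23 basal and mesenchymal markers, 10 were measured, and the rest stayed under 1 FPKM in both libraries. Among the 10 measured, 6 were higher and 2 lower (median 0.86, above all matched random medians). The median was 1.74 times as high with the 6 members at 5 FPKM or more. KRT17, TWIST1 and FN1 passed that filter only through the shRON library, which favours a higher median. KRT17 also passed the main filter of 1 FPKM only through shRON. KRT17 (0.523 to 5.54 FPKM, 2.10), TWIST1 (log2 ratio 2.06) and FN1 (2.86 to 13.9, 1.95) were higher from low levels, and S100A4 was lower (166 to 31.4, -2.36). Of 11 measured stem-cell-associated genes out of 19 listed, 6 were higher and 0 lower (median 0.59, percentile 99.98), led by SOX9 (26.9 to 78.6 FPKM, 1.51), CD44 (10.7 to 23.4, 1.06), KLF4 (8.17 to 18.0, 1.05) and ALDH1A3 (2.06 to 4.14, 0.75). Of 9 measured beta-catenin/TCF targets out of 18 listed, 5 were higher and 1 lower (median 0.67, percentile 99.94). DKK1 (0.304 to 8.21 FPKM, 2.82) and LEF1 (0.659 to 4.06, 1.61) were higher and CCND1, which encodes cyclin D1, lower (38.9 to 19.0 FPKM). DKK1 and LEF1 reached 1 FPKM only in the shRON library, which favours a higher median of the measured members. With only the 6 members at 5 FPKM or more, the beta-catenin median was 0.46 at percentile 97.3, inside the central range. DKK1 passed that filter, too, only through shRON. CD44 counts in the basal, stem-cell and beta-catenin lists, and CCND1 in the estrogen, beta-catenin and MAPK lists.

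Genes of the G1/S transition and DNA replication were lower. Of 23 members, 22 had log2 ratios below 0, 8 were at least 1.5-fold lower and 0 higher (median -0.53, below all matched random medians). GINS2 (58.1 to 24.1 FPKM, -1.24), the replication licensing genes CDC6 (13.7 to 5.53, -1.17) and MCM2 (22.4 to 9.90, -1.10, regional median -0.32), and E2F1 (16.3 to 8.33, -0.89) were lowest. Of 25 mitosis genes, 2 were lower by 1.5-fold, KIF11 (log2 ratio -0.75) and NUSAP1 (43.9 to 28.1, -0.63), and the median of -0.21 was at percentile 0.565. The mitosis median was -0.14 with the trend removed, and -0.09, at percentile 11.6, after regional medians were subtracted. Of 11 histone genes, 2 were lower, HIST1H2BK (246 to 133 FPKM, -0.88) and HIST1H4H (-0.68), with a median of -0.25 at percentile 6.03. After that subtraction it was -0.47 at percentile 0.04, and with the 8 members at 5 FPKM or more -0.38 at percentile 1.88.

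The medians of the signalling, apoptosis and p53 lists lay between -0.13 and 0.36. Of 9 measured MAPK feedback and output genes out of 17 listed, 4 were higher, among them DUSP4 (3.02 to 10.4 FPKM, 1.51) and SPRY1 (1.33 to 3.30, 0.88), and 1 lower (median 0.36, percentile 97.6), which was inside the central range with a pseudocount of 0.1 (97.3), with the trend removed (95.7) and with regional medians subtracted (88.6). Of 11 immediate-early genes, 3 were higher, BTG2 (3.94 to 9.25 FPKM, 1.05), KLF6 (0.75) and IER3 (0.71), and NR4A1 was lower (-0.77), with a median of 0.32 at percentile 98.4, or 97.1 at 5 FPKM or more. Of 15 apoptosis regulators, 2 were higher, BCL2L11 (1.94 to 4.56 FPKM, 0.92) and BMF (0.59), with a median of 0.31 at percentile 98.9, or 96.3 with the most abundant transcript only and 96.7 with regional medians subtracted. Of 16 p53 targets, 5 were lower, including CDKN1A (33.5 to 14.8 FPKM, -1.13) and PHLDA3 (22.8 to 10.7, -1.02), and 1 higher, BBC3 (5.14 to 9.23, 0.74). The p53 median of -0.13 was at percentile 6.98, or -0.27 at percentile 0.34 with the most abundant transcript only and -0.21 with members at 5 FPKM or more.

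Of 14 ER chaperone and unfolded-protein genes, 2 were lower by 1.5-fold, DNAJC3 (18.6 to 9.92 FPKM, -0.85) and HERPUD1 (26.6 to 15.7, -0.73), and 0 higher (median -0.33, percentile 0.93, or -0.21 at percentile 1.97 with the trend removed). Both lie among genes that were also lower, with regional medians of -0.51 and -0.79, and HERPUD1 relative to its region was at 0.06. The chaperone gene HSPA5 was at 279 and 204 FPKM (-0.45). Of 22 ATF4 and amino-acid stress genes, 6 were higher and 1 lower, with SLC7A11 (1.08), DDIT4 (39.2 to 82.4 FPKM, 1.05), SLC7A5 (153 to 279, 0.86) and ASNS (0.86) highest, and the median of 0.04 was at percentile 70.9. After regional medians were subtracted this median was 0.32, above all matched random medians. Of 10 heat-shock genes, 2 were higher, the near-identical HSPA1A (0.66) and HSPA1B (0.63), and 1 lower, BAG3 (-0.69), with a median of -0.32 at percentile 4.1, or 1.03 with regional medians subtracted, and -0.15 on the log2 scale with the trend removed. Of 10 TGF-beta and YAP targets, 3 were higher, ID3 (1.40), ID1 (1.33) and ID2 (1.29), and 0 lower, so the median of -0.12 (percentile 13.6) and the mean of 0.22 differed in sign. That median was -0.02 with regional medians subtracted and -0.01 at 5 FPKM or more. Of 71 ribosomal protein genes, 3 were lower, RPLP1 (-0.83), RPS2 (-0.71) and RPL4 (-0.68), and the median of -0.12 was at percentile 69.1, or 0.06 on the log2 scale with the trend removed and -0.22 with regional medians subtracted. Of 9 RNA interference genes, 2 were higher, EIF2C2 (0.80, regional median 0.52) and EIF2C4 (0.60), with a median of 0.25 at percentile 89.4, or 0.02 on the log2 scale with regional medians subtracted. In all, 29 lists had enough members, and 10 lay above the central range and 8 below it. For lists of randomly drawn genes, 1.45 would be expected outside. Listed genes share functions and may vary together, and lists share genes and are not independent, so the excess tests nothing. With a pseudocount of 5, which damps ratios of low genes by construction, the medians of the NF-kB (0.60), basal and mesenchymal (0.50), stem-cell (0.35), beta-catenin (0.28) and progesterone- and glucocorticoid-response (0.24) lists were more than 1.5 times smaller and stayed above the central range. The NF-kB median was 1.78 with a pseudocount of 0.1, and the hypoxia median -0.51 with regional medians subtracted.

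**Figure D2:**
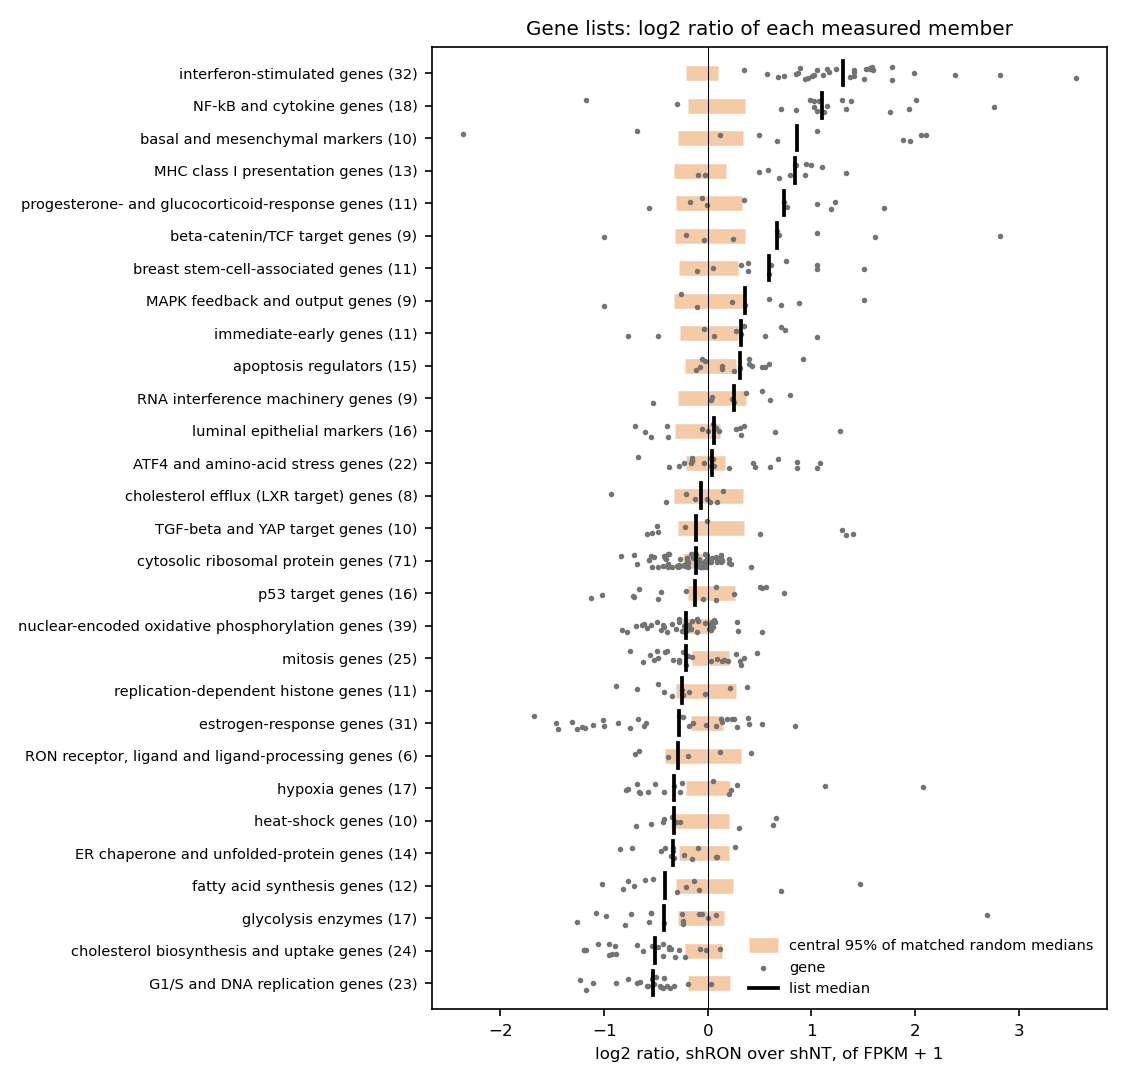
Log2 ratios (shRON over shNT, FPKM + 1) of the measured members of 29 gene lists, with 1 grey point per gene, a black bar at the list median, the number of measured members in brackets and an orange band for the central 95% of 10000 matched random medians. The interferon list has the highest median (1.30) and the G1/S list (-0.53) and the cholesterol list (-0.51) the lowest.

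Log2 ratios also followed chromosomal position. The medians of 258 bins of 10 Mb (12038 genes) had an SD of 0.23, against at most 0.10 in 1000 shuffles of the positions, and 44 bins lay 0.3 or more from the overall median against at most 7 in the shuffles. Of those 44 bins, 38 were lower and 6 higher. On chromosome 8, the 163 genes from 100 to 150 Mb had a median of 0.51, and 152 of them were above 0. Medians were lower on chromosome 16 from 40 to 60 Mb (65 genes, -0.73), on chromosome 13 from 90 to 120 Mb (58 genes, -0.58), on chromosome 9 from 60 to 110 Mb (110 genes, -0.49) and on chromosome 10 from 80 to 110 Mb (160 genes, -0.42). The part of chromosome 10 below 80 Mb was at 0.16. Smaller downward shifts ran over all of chromosome 5 (554 genes, -0.25), all of chromosome 15 (401 genes, -0.28) and chromosome 16 below 40 Mb (350 genes, -0.28). Chromosome 8 below 10 Mb was at -0.58 (17 genes). Chromosome 1 was at 0.16 up to 120 Mb and at -0.17 from 140 Mb, and chromosome 3 at 0.14 up to 90 Mb, the part that holds MST1R, and at -0.25 from 95 Mb. The bounds of these segments were chosen after the bins had been seen. After regional medians were subtracted, 376 genes were at least 2-fold higher and 214 lower, and the interferon, MHC class I, NF-kB, cholesterol, G1/S, estrogen-response and glycolysis lists stayed outside the central range on the same side.

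**Figure D3:**
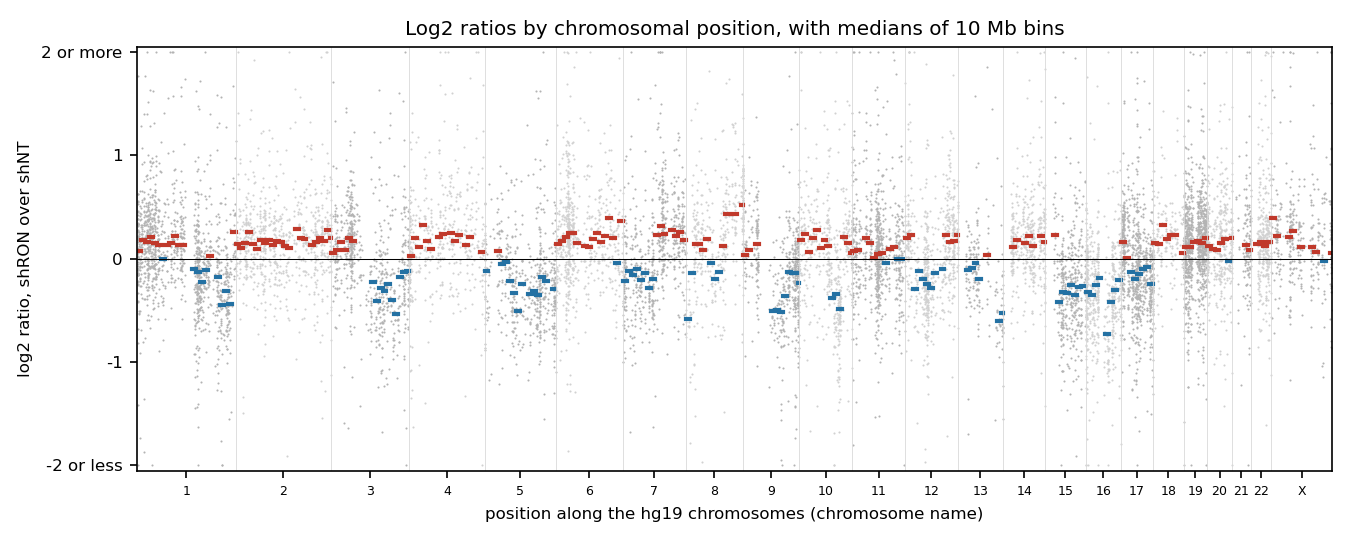
Log2 ratio (shRON over shNT, FPKM + 1) of each gene in grey against its hg19 position, chromosome by chromosome, with the median of each 10 Mb bin that has at least 15 genes as a red bar above 0 or a blue bar below 0. Genes beyond 2 or -2 are drawn at those limits; chromosome 8 from 100 to 150 Mb stands at a median of 0.51 and chromosome 16 from 40 to 60 Mb at -0.73.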

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

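The items here concern the small RNA genes, which the comparisons leave out, and the status column, which the main setting does not use, and no explanation was tested for them. Of the small RNA genes, 6 were listed at 0 in shNT and at 1 FPKM or more in shRON: SNORA8 at 64.2 FPKM, SNORA44 at 53.6, SNORA48 at 34.7, SNORA70 at 32.8, SNORA4 at 31.3 and SNORD17 at 3.70. In the other direction, 2 were listed at 0 in shRON, SNORA22 (28.5 FPKM in shNT) and SNORA67 (25.3). Transcripts with the status FAIL numbered 6 in shNT and 0 in shRON, and all 4 transcripts of DDX17 were among them. DDX17 therefore counts among the 415 higher genes although its level in shNT was not estimated.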

How the results depend on the processing

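No paired analysis was possible because each group has 1 library, and for the same reason none could be left out in turn. The alternative based on deposited intervals was not run, since the columns used hold none. The status, trend, fragment and regional settings were chosen after the data had been seen. The 415 higher and 271 lower genes were 696 and 490 with a pseudocount of 0.1, and 145 and 84 with a pseudocount of 5, which damps the ratios of low genes by construction. At 5 FPKM or more, 269 genes were higher, with fewer genes examined, and 190 lower. Equal totals gave 473 and 241, centring 391 and 306, and the other settings stayed within 1.5 times. MST1R was lower under every setting that gave it a value and was moved most, to -0.56, with regional medians subtracted. The beta-catenin median was 0.46 with members at 5 FPKM or more (percentile 97.3), where 6 of 9 members were left. Of 1249 values of single named genes under alternatives, 229 were counted as moved from the main value and 1 as reversed. With a pseudocount of 5, 73 named genes moved and 67 did not. With regional medians subtracted, 71 moved, 1 was reversed and 68 did neither. HERPUD1 went from -0.73 to 0.060 when its regional median, which is -0.79, was subtracted. Of 261 list medians under alternatives, 246 kept their side of the central range, 9 moved inside it, 6 moved outside it and 0 of those called changed sign. Depth limits genes near 1 FPKM, such as MST1 with an estimated 46.8 and 69.2 fragments.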

Other observations

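The gene families in this paragraph were grouped by name after their values had been seen. Of 73 cancer-testis antigen genes on the X chromosome, which are normally silent outside the germ line, 12 reached 1 FPKM, 6 of them in the shRON library alone, and 11 of the 12 were at least 2-fold higher in shRON (median log2 ratio 2.02), against 3.32% of all measured genes. Of the 6 that reached 1 FPKM in shNT, 5 were 2-fold higher and 0 lower, against 2.22% of all genes at that level in shNT. Since the family was picked for these values, the shares test nothing. Besides MAGEA6 and MAGEA12 they included CSAG1 (2.18 to 22.9 FPKM), GAGE2D (14.6 to 63.1) and MAGEA1 (2.48 to 6.31), and PAGE5 was listed at 0 in shNT and at 2.98 in shRON. Reads of MAGEA and GAGE genes are hard to assign to 1 copy, so single members are less certain than the group. All 3 measured AKR1C genes were at least 2-fold higher. Of 3 measured metallothionein genes on chromosome 16, MT1X was (2.08 to 23.6 FPKM), while MT2A (59.5 to 106 FPKM, 0.83) and MT1F (1.82 to 2.26, 0.21) were not, in a segment with a median of -0.73 over 65 genes. The S100 genes, most of them clustered on chromosome 1, went both ways: of 13 measured, 5 were at least 2-fold lower, including S100A16 (317 to 119 FPKM) and S100A10 (515 to 234), and 2 were higher, including S100A8 (34.0 to 96.6).

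In the paragraphs that follow, the tests of immune cells, of hairpin or culture, of other metabolic enzymes and of the correlation of next-door bins were chosen after their results had been seen, and the settings that remove the trend or the regional medians were added after the data had been seen. The interferon-stimulated genes kept a median log2 ratio of 1.37 with the trend in length, GC content and expression removed and 1.14 with regional medians subtracted. Both lay above all matched random medians, which argues against either as the whole cause. What was removed was small. The trend explained 1.76% of the variance of log2 ratios, and the regional medians of the interferon-stimulated genes had a median of 0.16. Immune cells mixed into the shRON culture are argued against as the whole cause by 9 of 13 immune cell markers that were listed at 0 there, among them PTPRC, LYZ, TYROBP and FCER1G, although CD68 (1.37 to 5.84 FPKM), CD14 (0.115 to 0.879) and ITGAM (0.0259 to 0.119) were higher in shRON. A response to the hairpin or to the culture cannot be told apart from a response to lower RON, since there is 1 shRON library with 1 hairpin. The hypothesis that lower RON raises these genes therefore stays untested.

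For the cholesterol genes, the median was -0.46 with the trend removed and -0.65 with regional medians subtracted, both below all matched random medians. The regional medians of these genes had a median of 0.11, so subtracting them tends to lower the list median. The median of oxidative phosphorylation genes (-0.21, 39 genes) was 0.30 above that of the cholesterol genes, with a standard error across genes of 0.12, which argues against an equal shift of those 2 lists in these libraries. Glycolysis (-0.42) and fatty acid synthesis genes (-0.41) had a pooled median only 0.094 above that of the cholesterol genes, with a standard error of 0.21, so a lower level shared with them cannot be told apart from one of the cholesterol genes. Both standard errors treat genes as independent and cover no difference between cultures. That lower RON reduces the pathway is a hypothesis that 1 library per group leaves untested, beside a difference between the cultures.

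The shifts of whole regions may come from a difference in chromosome copy number between the 2 cultures. Medians of next-door 10 Mb bins correlated with a Spearman rho of 0.69 (204 pairs, at most 0.19 when bins were shuffled), as shifts over many megabases would give. A trend with length, GC content or expression is argued against by an SD of bin medians of 0.234 after its removal, and reads shared between near-identical genes by 47 neighbouring pairs with different name stems that were 2-fold shifted in the same direction, against at most 31 in shuffles. Around KCTD3 and KCNK2, the 6 other expressed genes within 2 Mb had a median of -0.38 (standard error 0.15) and ranged from -0.92 to -0.10. These values argue against an equal loss of that whole region as the whole cause for KCTD3 and KCNK2. They cannot speak to a smaller loss that covers only KCTD3 and KCNK2, which would leave the other genes as they are. DNA was not analysed here, and regional differences in chromatin stay open.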
